A study of Mus musculus with 6 samples.

How the data were processed

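Polyadenylated RNA of luminal epithelial cells, the milk-producing and duct-lining cells of the mammary epithelium, was sequenced in 6 mouse libraries, 3 from wild-type control mice and 3 from mice lacking Ocln, all taken at 7 weeks of age, per the labels. RNA was extracted with a kit from Magen and the libraries were made by GENEWIZ, per the labels' protocols. How the luminal cells were isolated, whether each library came from a separate mouse, and the genetic background of the strains are not given in the sources used here. The p-values per gene therefore measure the spread between these libraries, part of which may be technical. Those of tests over lists or sets of genes compare genes within the same comparison and do not measure the spread between libraries.

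The data used here are the authors' deposited table of 1 comparison, knockout over control, with 16701 genes named by symbol. The submitters' processing notes name DESeq2, without a version, and the mouse build mm10 (GRCm38). The aligner, the read counter, the gene annotation and the model formula are not given in the sources used here. Per the file headers, the authors' table gives for each gene a mean level, which is a signal in normalized counts averaged over the libraries, the log2 fold change and its standard error (SE, in log2 units), the Wald statistic, which is a score, the p-value and the adjusted p-value. A last column holds another kind of value, the authors' call of Up, Down or Stable. The direction of the comparison was taken from the name of the deposited table.

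The values of the table were checked against each other. The Wald score equalled the log2 fold change over its SE to within 2.6e-07, so the deposited fold changes are not shrunken. The deposited p-values differed from a normal tail of that score by at most 0.41 percent, and the deposited adjusted p-values from a Benjamini-Hochberg adjustment over the listed genes by at most 0.51 percent. The authors' calls matched, with 0 exceptions, a rule of unadjusted p under 0.05 with an absolute log2 fold change above 1.013, the mean plus 2 SD of the absolute log2 fold changes. The lowest mean level listed was 8.35, so genes below that level were not analysed here.

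No values per library were used here. The design fixed before the data were examined named a count model of its own for tables of counts and, for a table without values per library, a description of the authors' fold changes and adjusted p-values with no new test per gene. That description is what is given. The depth of each library is unknown, and no principal components, no values of Ocln per library, no exact permutation test and no other splits of the 6 libraries could be had. The precision of each fold change is that of the authors' SE, whose median was 0.60 in the lowest of 5 equal bins of mean level and 0.17 in the highest. Intervals of 95 percent were taken as 1.96 SE on either side on the log2 scale.

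Gene groups were 36 lists fixed in advance, 26 of pathways, states and neighbouring genes and 10 of markers of other cell types that a luminal preparation could hold. They were tested with cameraPR of limma 3.58.1 under R 4.3.3 on the Wald score, with a preset correlation of 0.01 between genes, two-sided, and Benjamini-Hochberg adjustment over the 36 lists. This replaced the planned camera test on values per library. A correlation could not be estimated from 1 table, so the test was repeated with a preset correlation of 0.05. Beside each list stand the members called at an adjusted p under 0.05 over all genes, and, where these differ, those called when the p-values were adjusted over the list alone, which for tight junction components is not reported. A list's median log2 fold change was also placed among 10000 random lists matched on mean level in 100 bins. Other settings were ranks of the score, genes with a mean level of at least 50, members of more than 1 list left out, and scores less their median in each of 20 bins of transcript length. For the calls per gene, other settings were a stricter adjusted p of 0.01, an absolute log2 fold change of at least 1, the filter at a mean level of 50, the authors' own calls, scores divided by the square root of their inflation factor, the length correction, and genes within 5 Mb of Ocln left out. The settings of the list test and the last 4 for genes were chosen after seeing the data.

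Genes are named in the text by a rule fixed with the lists. It takes Ocln and Rab11fip5, the gene of its partner FIP5. It takes the 12 largest rises and the 12 largest falls past an adjusted p of 0.05 among genes in the upper part of the mean levels, predicted genes and receptor segments left out. It takes up to 4 called members of each list, and the 2 members with the highest mean level of the junction, endosome, spindle, G2/M, luminal and other cell type lists. The part of the rule that asks for libraries without overlap between genotypes could not be applied. Other genes named were chosen after their values were seen. Coordinates, gene types and transcript lengths come from GENCODE vM21 on GRCm38, matched by symbol for 16225 of the 16701 genes (97.1 percent).

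Computations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9. The scripts were tested on simulated data for this comparison, over 16701 genes. The authors' SE were used for single genes, and scores drawn from a normal distribution for lists. At an adjusted p under 0.05 they recovered 62 of 100 genes changed by a log2 fold change of 1 and 83 of 100 changed by 2, with 6 unchanged genes called. Of 5 lists shifted by 1 unit of the score, 4 were called, and of 31 lists left as they were, 0 were called. The list scores were drawn independently, without correlation between members or the inflation of the real scores. They therefore do not measure how often lists are falsely called here.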

Results

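Occludin, encoded by Ocln, is a membrane protein of tight junctions, the seals between epithelial cells. The series asks what occludin and FIP5, a partner of the recycling endosome protein Rab11, do for the mitotic spindle, and its RNA-seq part compared luminal epithelial cells of the mammary gland in 3 libraries from control mice and 3 from Ocln knockout mice at 7 weeks of age. The authors' deposited table lists 16701 genes with mean levels from 8.35 to 242422 normalized counts, the highest being mt-Co1. The mean levels sum to 23524937 normalized counts, of which the 10 highest genes hold 6.2 percent. The depth of each library is unknown.

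Ocln itself was lower in the knockout. The authors' deposited table gives it a log2 fold change of -1.15 ± 0.16 (SE, DESeq2 adjusted p = 4.36e-09) at a mean level of 2048 normalized counts. This is 44.9 percent of the control level, with a 95 percent interval of 35.9 to 56.2 percent. The gene lies on the minus strand of chromosome 13, from 100496507 to 100552718 on GRCm38, and the table does not show which of its exons the remaining reads came from. Rab11fip5, which encodes FIP5, had a log2 fold change of 0.54 ± 0.22 in the authors' deposited table and did not pass (adjusted p = 0.317, unadjusted DESeq2 p = 0.012). This is 145.4 percent of the control level, with a 95 percent interval, not adjusted for the number of genes, of 108.6 to 194.7 percent.

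Across the listed genes, 181 had an adjusted p under 0.05 in the authors' deposited table, 135 of them higher and 46 lower in the knockout. Bnip5 (log2 fold change 2.87 ± 0.27 SE, a 7.33-fold rise) and Ifi202b (2.86 ± 0.37, 7.25-fold), an interferon-inducible DNA-binding protein of the p200 family, rose most in the authors' deposited table among genes in the upper part of the mean levels, from which the naming rule takes the 12 largest changes of each direction. Next among these in the authors' deposited table were Ltf (2.59 ± 0.29, 6.02-fold), which encodes the iron-binding milk protein lactoferrin, and Gabrg3 (2.30 ± 0.26), a subunit of the GABA-A receptor. Naip6, an intracellular sensor of bacterial flagellin, followed at 1.97 ± 0.32 in the authors' deposited table, and the signalling adaptor gene Pik3ap1 at 1.73 ± 0.35. The planar polarity gene Prickle1 (1.72 ± 0.27), the ephrin receptor gene Epha4 (1.56 ± 0.36), Ccdc141 (1.54 ± 0.33) and the galactolipid enzyme gene Ugt8a (1.48 ± 0.26) rose too, per the authors' deposited table. Ttpa, which encodes a vitamin E transfer protein (1.45 ± 0.25), and Atp10b, a phospholipid-transporting ATPase (1.42 ± 0.32), complete the 12 rises taken from the authors' deposited table. Adjusted p-values of these 12 rises in the authors' deposited table ran from 1.06e-21 for Bnip5 to 0.00317 for Epha4.

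Apod, the gene of apolipoprotein D, fell most in the authors' deposited table among the genes in that upper part, with a log2 fold change of -2.11 ± 0.24 (SE), or 0.232 times the control level. Grb14, an adaptor of the insulin receptor (-1.21 ± 0.29), Cdo1, the cysteine dioxygenase gene (-1.20 ± 0.31), Ocln and Csn3, the gene of kappa-casein (-1.15 ± 0.31), followed among these in the authors' deposited table. Lower levels were also listed in the authors' deposited table for the basement membrane collagen gene Col4a1 (-1.04 ± 0.29), Id3, an inhibitor of helix-loop-helix transcription factors (-0.97 ± 0.20), and Cldn8, a tight junction claudin (-0.94 ± 0.20). The remaining falls taken from the authors' deposited table were Col9a1 (-0.94 ± 0.22), Hacd4 (-0.94 ± 0.27), the methionine sulfoxide reductase gene Msrb3 (-0.92 ± 0.19) and Clec2d (-0.91 ± 0.26). Adjusted p-values of these 12 falls in the authors' deposited table ran from 2.38e-15 for Apod to 0.0442 for Clec2d. The authors themselves called 466 genes in the deposited table, 301 up and 165 down, on the unadjusted p, and 114 of those had an adjusted p under 0.05. After the scores were divided by their inflation, 119 genes passed, and Cdo1, Csn3, Col4a1, Hacd4 and Clec2d among the named falls did not. With a log2 fold change of at least 1 in size required as well, 117 of the 181 genes were left, 83 higher and 34 lower.

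**Figure D1:**
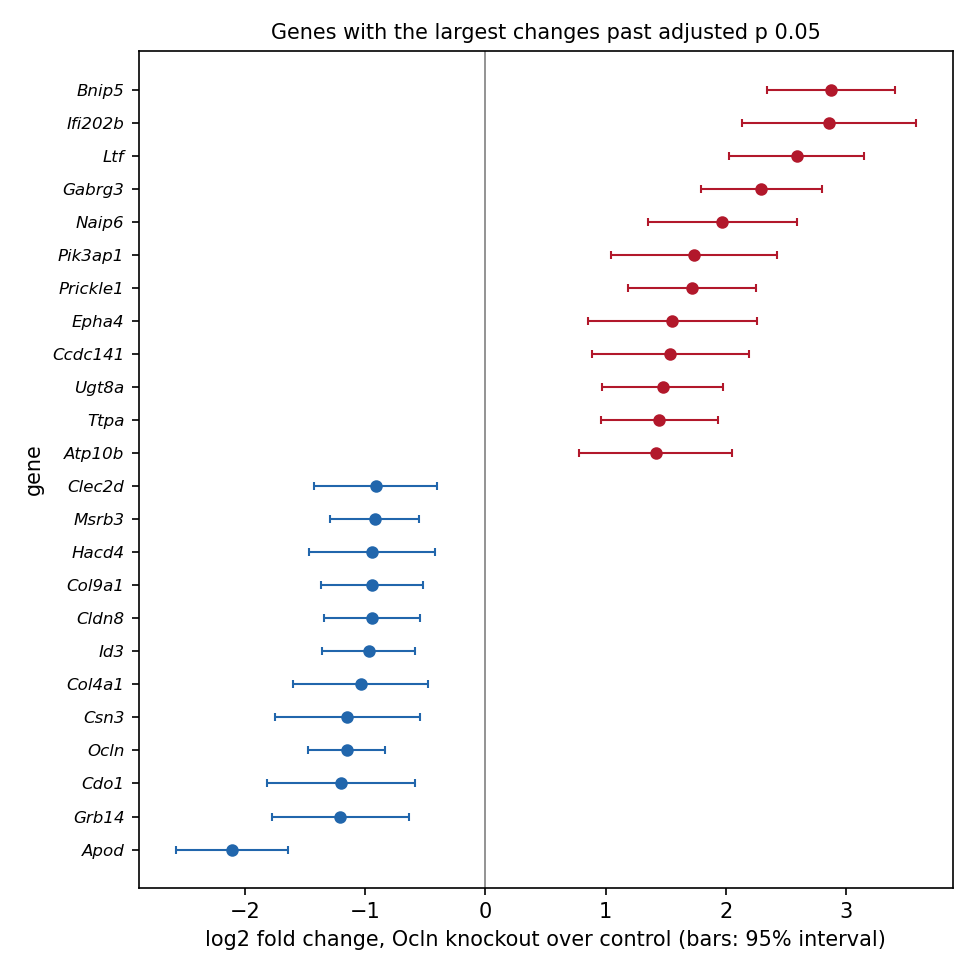
Log2 fold change (knockout over control, horizontal axis) of the 24 genes with the largest changes in the upper part of the mean levels, 12 higher in red and 12 lower in blue. Points are the values of the authors' deposited table and bars are 95 percent intervals from its standard errors. Bnip5 lies highest at 2.87 and Apod lowest at -2.11.

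The gene groups nearest to the question of the series were junctions, recycling endosomes and the spindle. Of 22 tight junction components, 2 fell, Ocln and Cldn8, and 0 rose, while 17 had a positive log2 fold change and, at an unadjusted p under 0.05, 6 were higher and 2 lower. The median log2 fold change of the list was 0.19 (cameraPR adjusted p = 0.0749), and it passed when ranks of the score were used (adjusted p = 0.00596). Ocln, the deleted gene, is a member, and its strongly negative score pulls against an upward shift of the list. The list was not tested without Ocln, so the main test does not show that the other members were unshifted. The members with the highest mean level, the claudin genes Cldn4 (0.00 ± 0.20 SE) and Cldn3 (0.21 ± 0.18), did not pass in the authors' deposited table. Of 22 genes of adherens junctions, desmosomes and epithelial polarity, 0 passed the DESeq2 test, 2 having an unadjusted p under 0.05, both positive, and the list was shifted upward by a median of 0.08 (cameraPR adjusted p = 0.0364). That shift was lost with a preset correlation of 0.05 (adjusted p = 0.156), without members shared with other lists (adjusted p = 0.053) and after the trend with transcript length was taken out (adjusted p = 0.11). Among 26 genes of the recycling endosome and Rab11 pathway, 0 passed DESeq2, 2 had an unadjusted p under 0.05 in the positive direction, Rab11fip5 among them, and the median was 0.03 (cameraPR adjusted p = 0.341). Rab11fip1 (0.34 ± 0.19) and Rab10 (-0.14 ± 0.15), the members with the highest mean level in the authors' deposited table, did not pass.

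Genes of cell division were shifted downward as groups, while no single member passed. Of 33 G2/M genes, which peak around mitosis, all had a negative log2 fold change, with a median of -0.93, and the list passed (cameraPR adjusted p = 3.44e-15). By the authors' DESeq2 test 0 of them passed over all genes, 21 had an unadjusted p under 0.05, and 2, Ccnb2 and Cenpf, passed when adjusted over the list alone. The median SE of the G2/M members was 0.45 against 0.26 in lists matched on mean level, at percentile 100. Their values may therefore differ between libraries of 1 genotype. Top2a (-0.93 ± 0.64 SE) and Mki67 (-1.09 ± 0.62), a topoisomerase gene and the Ki-67 gene of cycling cells, had the highest mean levels of the list in the authors' deposited table. The 36 measured genes of the mitotic spindle, dynein and the spindle pole had a median of -0.44 (cameraPR adjusted p = 4.97e-05), with 0 passing DESeq2 and 11 at an unadjusted p under 0.05, all of them negative. Of the members, 25 had a negative and 11 a positive log2 fold change. This list joins dynein genes with genes of dividing cells, and these parts were not tested apart. Its shift therefore shows neither a fall of dynein genes nor a result separate from the G2/M shift. The median SE of the spindle list was 0.28 against 0.22 in lists matched on mean level, at percentile 100, so its values may differ between libraries of 1 genotype. Its members with the highest mean level in the authors' deposited table were Dync1h1, the heavy chain of cytoplasmic dynein (0.06 ± 0.17), and Gnai2 (-0.11 ± 0.16). Racgap1 (-0.92 ± 0.32) and Kif23 (-0.98 ± 0.37), which work in the midzone of the dividing cell, were chosen after the values of the authors' deposited table were seen. The 41 G1/S and DNA replication genes had a median of -0.25 (cameraPR adjusted p = 0.00714), with 0 passing DESeq2 and 3 negative at an unadjusted p under 0.05, and its median SE was 0.29 against 0.23 in matched lists, at percentile 100. That call was lost with a preset correlation of 0.05 (adjusted p = 0.103). The 22 measured p53 targets had a median of -0.10 (cameraPR adjusted p = 0.374), with 0 at an adjusted or unadjusted p under 0.05 by DESeq2.

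Luminal progenitor genes were shifted upward as a group. Of 20 measured luminal progenitor genes, which mark luminal cells without hormone receptors, 4 rose and 1 fell. The rises in the authors' deposited table were Ltf, the transferrin gene Trf (0.99 ± 0.26 SE, 1.99-fold), Mfge8, which encodes a milk fat globule protein (0.95 ± 0.26), and Wfdc18 (0.88 ± 0.25), and the fall was Csn3. After the scores were divided by their inflation, Ltf still passed, and Trf (adjusted p = 0.0679), Mfge8 (0.077), Wfdc18 (0.131) and Csn3 (0.0759) did not. Adjusted over the list alone, 10 rose and 1 fell, and the list was shifted upward (median 0.59, cameraPR adjusted p = 1.1e-09). Without the 7 members that stand in other lists too, its adjusted p was 5.76e-07. Further members in the authors' deposited table, which did not pass, were the progenitor transcription factor genes Elf5 (0.51 ± 0.17) and Ehf (0.75 ± 0.24), Aldh1a3 (0.72 ± 0.26) and Kit (0.36 ± 0.20). The 21 measured hormone-sensing luminal genes were shifted downward (median -0.40, cameraPR adjusted p = 0.0227), with 0 passing DESeq2 and, at an unadjusted p under 0.05, 1 higher and 2 lower. This call was lost with a preset correlation of 0.05 (adjusted p = 0.103). Ptn (-0.60 ± 0.29) and the prolactin receptor gene Prlr (-0.40 ± 0.26) had its highest mean levels, and Esr1, the estrogen receptor gene, stood at -0.69 ± 0.58 in the authors' deposited table.

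Of 18 pan-luminal keratins and epithelial markers, 1 rose, the epithelial transcription factor gene Ovol1 (0.88 ± 0.16 SE), while Krt18 (-0.10 ± 0.15) and Krt8 (-0.06 ± 0.14) did not pass in the authors' deposited table. The list had a median of 0.07 (cameraPR adjusted p = 0.177). Of 19 measured milk protein and lipid secretion genes, 4 rose, Ltf, Mfge8, Muc1 (1.15 ± 0.29) and Muc15 (1.09 ± 0.30) in the authors' deposited table, and 1 fell, Csn3. Adjusted over the list alone, Btn1a1 rose as well, and Muc15 lost its call after the scores were divided by their inflation (adjusted p = 0.0931). This list had a median log2 fold change of -0.19 and a mean of -0.24 but a mean Wald score of 0.52, so its signs differ, and it did not pass (cameraPR adjusted p = 0.177). It shares 3 of its members with other lists, and without shared members its adjusted p was 0.927. Of 23 measured fatty acid synthesis and lipid droplet genes, Acsl1, an acyl-CoA synthetase gene (1.04 ± 0.24), rose and Srebf1, a master regulator of lipid synthesis (-0.74 ± 0.18), fell in the authors' deposited table. That list had a median of -0.09 (cameraPR adjusted p = 0.522). Among 25 measured Notch and Wnt pathway genes, the receptor gene Notch1 rose (0.76 ± 0.20) and Lgr5, a Wnt-responsive stem cell receptor gene, fell (-2.28 ± 0.42) in the authors' deposited table. Notch1 lost its call after that division (adjusted p = 0.0668) and after the trend with transcript length was taken out (adjusted p = 0.0735). Adjusted over the list alone, Heyl, Lgr6 and Axin2 rose too, and the median was 0.08 (cameraPR adjusted p = 0.247).

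Inflammatory genes and markers of immune cells were shifted upward. Of 26 measured NF-kB and inflammatory genes, 0 passed the DESeq2 test, but 14 were higher and 1 lower at an unadjusted p under 0.05, and 11 rose and 1 fell when adjusted over the list alone. The list passed (median 0.58, cameraPR adjusted p = 8.62e-09), and the median SE of its members was 0.30 against 0.20 in lists matched on mean level. Examples chosen after the values were seen are Tnfaip2 (0.90 ± 0.26 SE), Tnf (0.76 ± 0.23) and the neutrophil chemokine gene Cxcl2 (0.94 ± 0.33) in the authors' deposited table, against Il33 at -2.23 ± 0.79. Markers of other cells moved with it. Of 23 macrophage and myeloid markers, 1 rose, S100a8 (2.12 ± 0.53 in the authors' deposited table, at a mean level of only 37.5), and the list was shifted upward (median 0.44, cameraPR adjusted p = 1.05e-06). Adjusted over the list alone, 3 of them rose, S100a8, S100a9 and Lyz2. Lyz2 (0.97 ± 0.29) and Cd14 (0.33 ± 0.18), its members with the highest mean level in the authors' deposited table, did not pass over all genes, and luminal progenitor cells express Cd14 too. The 11 measured B and plasma cell markers had a median of 1.65 (cameraPR adjusted p = 0.000525) and the 12 measured T and NK cell markers a median of 0.73 (cameraPR adjusted p = 0.0325, lost at a preset correlation of 0.05 with adjusted p = 0.103). The median SE of the B and plasma cell markers was 1.32 against 0.48 in lists matched on mean level, at percentile 100, so their values are imprecise and may differ between libraries of 1 genotype. Of the 2 lists, 0 B cell and 1 T and NK cell marker stand in another list. In each of these lymphocyte lists 0 members passed DESeq2 and 1 was higher at an unadjusted p under 0.05. Levels were low, the highest in the authors' deposited table being Ighm (1.58 ± 1.15, mean level 195), Ighd (2.58 ± 1.32, mean level 68.0), Trbc2 (0.22 ± 0.47, mean level 132) and Ccl5 (1.12 ± 0.65, mean level 65.3).

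The 39 interferon-stimulated genes had a median of 0.12 (cameraPR adjusted p = 0.0364), which was lost at a preset correlation of 0.05 (adjusted p = 0.211). By DESeq2, 0 passed, 5 were higher and 1 lower at an unadjusted p under 0.05, and Phf11d (0.70 ± 0.22 in the authors' deposited table) rose when adjusted over the list alone. The 17 MHC class II and antigen presentation genes had a median of -0.11 (cameraPR adjusted p = 0.32), with 0 passing DESeq2 and 3 lower at an unadjusted p under 0.05. Of 28 immediate early and dissociation response genes, 1 rose, the transcription factor gene Egr3 (1.26 ± 0.31 in the authors' deposited table), and the median was -0.01 (cameraPR adjusted p = 0.818). The 16 heat shock genes had a median of -0.04 (cameraPR adjusted p = 0.259), and by DESeq2 0 passed over all genes while 2 were lower at an unadjusted p under 0.05, Hspa1a and Hspa1b, which also passed when adjusted over the list alone and share near-identical reads.

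**Figure D2:**
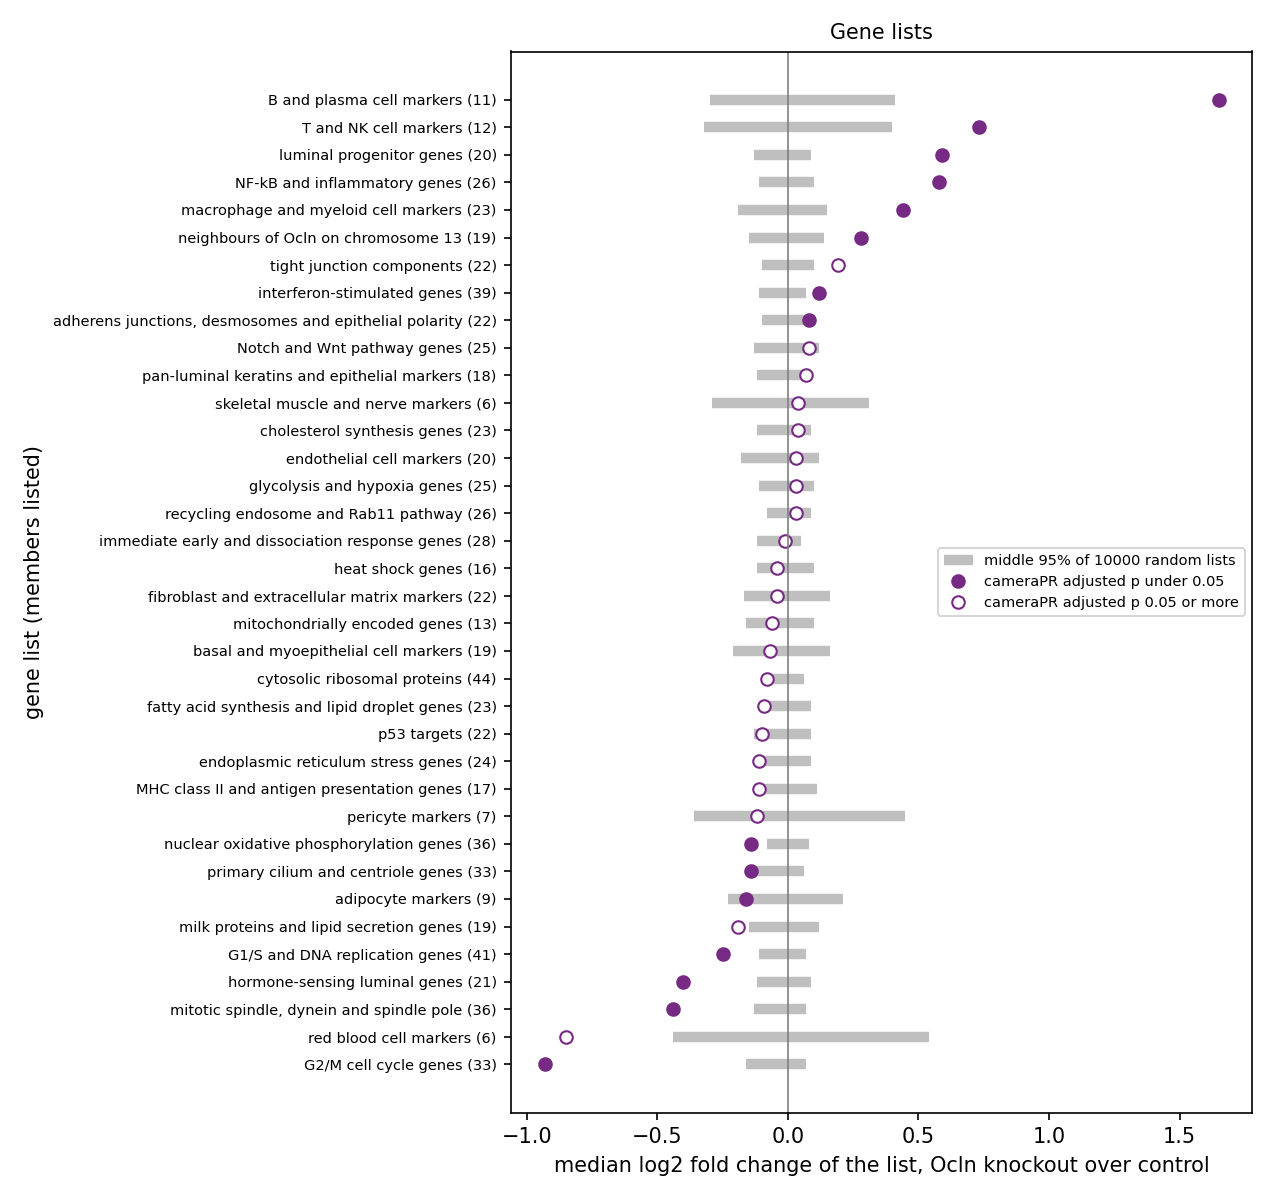
Median log2 fold change (knockout over control, horizontal axis) of each of the 36 gene lists, with the number of members listed in parentheses. Filled points passed the cameraPR test, open points did not, and grey bars hold the middle 95 percent of 10000 random lists matched on mean level. B and plasma cell markers lie highest at 1.65 and G2/M genes lowest at -0.93.

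Of the energy metabolism lists, 1 passed. The 36 nuclear oxidative phosphorylation genes all had a negative log2 fold change, with a median of -0.14 (cameraPR adjusted p = 0.000525), while 0 had an adjusted or unadjusted p under 0.05 by DESeq2. Atp5b, an ATP synthase subunit gene, had a value of -0.14 ± 0.19 (SE) in the authors' deposited table. The Wald score rose with transcript length over the 16225 genes with a known length (Spearman rho 0.184 across genes, which are not independent replicates), from a median of -0.29 in the shortest of 20 bins to 0.45 in the longest. After that trend was taken out, the oxidative phosphorylation list had an adjusted p of 0.00859. The 13 mitochondrially encoded genes (median -0.06, cameraPR adjusted p = 0.416) and the 44 cytosolic ribosomal protein genes (median -0.08, adjusted p = 0.416) did not pass, and 0 of their members had an unadjusted p under 0.05 by DESeq2. The 33 primary cilium and centriole genes had a median of -0.14 (cameraPR adjusted p = 0.0364), with 0 passing DESeq2 and 1, Ift80, at an unadjusted p under 0.05. Their call was lost at a preset correlation of 0.05 (adjusted p = 0.199) and among genes with a mean level of at least 50 (adjusted p = 0.0544). Cholesterol synthesis (23 genes, median 0.04, cameraPR adjusted p = 0.699), endoplasmic reticulum stress (24 genes, median -0.11, adjusted p = 0.172) and glycolysis and hypoxia genes (25 genes, median 0.03, adjusted p = 0.879) did not pass. By DESeq2 0 of these 3 lists' members passed, and at an unadjusted p under 0.05 the first 2 had 1 lower gene each and the last 0.

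Among the remaining markers of other cell types, 2 genes fell. Of 19 basal and myoepithelial markers, 1 fell, the oxytocin receptor gene Oxtr (-1.55 ± 0.38 SE), while Vim (0.39 ± 0.26) and Acta2, the smooth muscle actin gene (-0.16 ± 0.28), did not pass in the authors' deposited table. The list had a median of -0.07 (cameraPR adjusted p = 0.522). Of 22 measured fibroblast and extracellular matrix markers, 1 fell, the decorin gene Dcn (-1.36 ± 0.35), while Col6a3 (-0.09 ± 0.33) and Gsn (0.74 ± 0.35) did not pass in the authors' deposited table. Their median was -0.04 (cameraPR adjusted p = 0.809). The 9 measured adipocyte markers had a median of -0.16 (cameraPR adjusted p = 0.0329), lost at a preset correlation of 0.05 (adjusted p = 0.102), with 0 passing DESeq2 and 2 lower at an unadjusted p under 0.05. Pnpla2 (-0.12 ± 0.16) and Lipe (-0.11 ± 0.21), lipase genes, had the highest mean levels of that list in the authors' deposited table. The 20 endothelial markers (median 0.03, cameraPR adjusted p = 0.416), 6 measured skeletal muscle and nerve markers (median 0.04, adjusted p = 0.663), 7 measured pericyte markers (median -0.12, adjusted p = 0.699) and 6 measured red blood cell markers (median -0.85, adjusted p = 0.0707) did not pass. By DESeq2 0 of their members passed over all genes. At an unadjusted p under 0.05, 1 endothelial and 1 muscle and nerve marker were higher and 1 red blood cell marker, Hba-a1, was lower, which also fell when adjusted over its list alone. Their highest members in the authors' deposited table were Vwf (0.22 ± 0.20), Eng (-0.50 ± 0.31), Sox10 (0.48 ± 0.19), Mbp (0.18 ± 0.17), Notch3 (0.16 ± 0.14), Mcam (-0.12 ± 0.19), Hba-a1 (-1.76 ± 0.56) and Hbb-bs (-1.88 ± 1.40), the last pair having near-identical copies that share reads. Sox10, the muscle and nerve marker counted as higher, and Notch3 had mean levels of 4866 and 7131, against medians of 114 and 25.2 in their lists. Their levels therefore do not stand for those lists.

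Genes beside Ocln on chromosome 13 leaned upward as a list, in which Naip genes had the 2 calls. Of 19 measured neighbours, a list without Ocln itself, 13 had a positive and 6 a negative log2 fold change, 2 rose, Naip6 and Naip5, and 0 fell, and adjusted over the list alone Marveld2 and Naip1 rose too. Naip1 had a mean level of only 8.55 in the authors' deposited table, near the lowest listed. Its 95 percent interval ran from 159.1 to 2671.4 percent of the control level. In the authors' deposited table Naip5, another sensor of flagellin, had a log2 fold change of 1.96 ± 0.39 (SE, 3.90-fold, adjusted p = 0.000184) and lies from 100211739 to 100246323, and Naip6 lies from 100281121 to 100317674, both on the minus strand of GRCm38. The list was shifted upward (median 0.28, cameraPR adjusted p = 0.00391), which was lost when ranks of the score were used (adjusted p = 0.101). The genes next to Ocln on either side, Gtf2h2 (0.09 ± 0.19) and Marveld2 (0.51 ± 0.15), which encodes the tight junction protein tricellulin, did not pass over all genes in the authors' deposited table. Naip genes are near-identical copies between which reads can be split, so their values are uncertain. All Naip genes of the list were positive, so the 6 negative values belong to its other members. Those lay on both sides of 0, from Ccnb1 (-1.17 ± 0.54) to Mrps36 (1.25 ± 0.59) in the authors' deposited table. The list was not tested without its Naip genes, so a shift of the whole region is not shown.

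**Figure D3:**
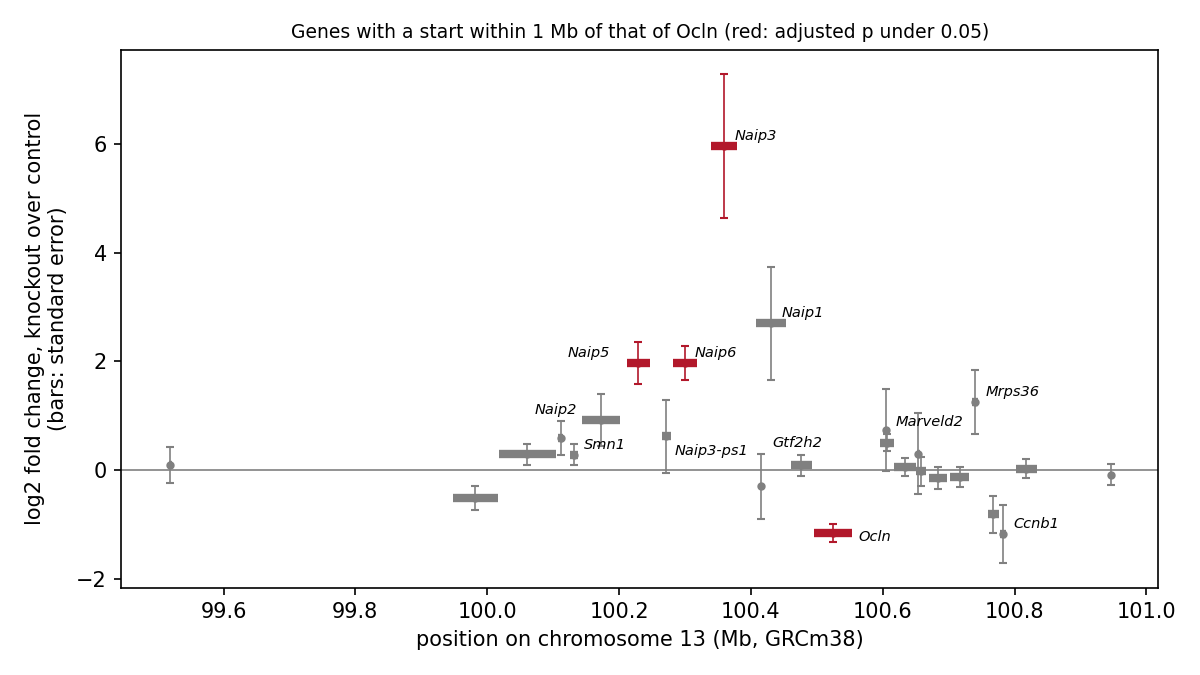
Log2 fold change (knockout over control, vertical axis) against position on chromosome 13 (GRCm38, in Mb) for the genes that start within 1 Mb of the start of Ocln. Thick bars span each gene, thin bars are the standard errors of the authors' deposited table, and red marks an adjusted p under 0.05. Naip5, Naip6 and Naip3 lie above 0 and Ocln below, at -1.15.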

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

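All settings given here except the thresholds and the filter on mean level for genes were chosen after seeing the data. The settings that need values per library were not run, namely the edgeR, DESeq2 and limma-voom fits, other normalizations, no filter, another pseudocount, leaving out single libraries, fry, and camera with an estimated correlation. No paired analysis was possible because the table holds no values per library. The precision is limited by 3 libraries per genotype: at the median SE of 0.23, a log2 fold change of 0.80 was needed to pass.

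The 181 called genes became 107 at an adjusted p under 0.01, 117 with a log2 fold change of at least 1 in size, 119 after the scores were divided by their inflation (factor 1.18) and 466 by the authors' own calls. By their construction the first 3 keep a subset of the 181, whereas 114 of the authors' calls are among the 181. The share of higher genes was 74.6 percent and, with the authors' calls, 64.6 percent. With a mean level of at least 50, 178 genes were called (165 of the 181), after the trend with transcript length was taken out 175 (152 of the 181), and without the genes near Ocln 173 (each among the 181). Ocln passed under each of these settings that gave it a value, at -1.15. Of the other named genes, 14 lost their call with inflation, 5 with the length trend taken out and 2 without the genes near Ocln, while 4 gained one with the length trend and 1 with the filter. Gained with the length trend taken out were Cenpf (adjusted p = 0.0244), S100a9 (0.0371), Tnf (0.039) and Lyz2 (0.0389). The filter added Tnfaip2 (adjusted p = 0.0438).

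Of 36 lists, 15 passed. With a preset correlation of 0.05, 8 passed, all of them among the 15, and 7 were lost: adherens junctions, G1/S, interferon, hormone-sensing, cilium, adipocyte and T and NK cell lists. Ranks of the score gave 15 lists, the filter 13 (of 31 tested, without the B and plasma cell and the T and NK cell lists), members of more than 1 list left out 14, the length trend taken out 14 and random lists 17 (13 of the 15). Lost against random lists were the adherens junction list, at percentile 95.37, and the adipocyte list, at percentile 8.41. Tight junctions passed upward with ranks, and their median lay at percentile 99.96 of random lists. Milk proteins passed upward with the filter (adjusted p = 0.0331), whereas their median of -0.19 lay low among random lists, at percentile 0.86, so these settings differ in direction. The causes were not tested.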

Other observations

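The tests in this part were chosen after the result was seen, except the count of neighbouring called genes and both tests of transcript length. The hormone-sensing and G1/S list tests repeated here are those of the fixed lists, and only their use to weigh causes was chosen after. The genes named here were chosen after their values in the authors' deposited table were seen. Of single genes expressed by neutrophils, Ngp (3.78 ± 0.65 SE) and Chil3 (2.68 ± 0.71) rose in the authors' deposited table, at mean levels of 79.7 and 35.6, while S100a9 (1.89 ± 0.57) did not pass, and no list of such genes was tested. Chil3 lost its call after the scores were divided by their inflation (adjusted p = 0.066). In a block of interferon-inducible p200 genes on chromosome 1, from 173350879 to 174031810 on GRCm38, 9 genes were listed and 8 had a positive value. Ifi202b, Ifi203 (2.11 ± 0.43) and Ifi204 (1.76 ± 0.49) rose there in the authors' deposited table, and Aim2, a sensor of cytosolic DNA, fell (-1.03 ± 0.30, adjusted p = 0.0499). Ifi204 (adjusted p = 0.0927) and Aim2 (adjusted p = 0.133) lost their calls after the scores were divided by their inflation, and Aim2 also with the length trend taken out (adjusted p = 0.059) and without the genes near Ocln (adjusted p = 0.0511). These are related copies, so reads can be split between them. The strains are not given in the sources used here, so a strain difference in this block, Ifi202b included, cannot be told apart from an effect of the knockout.

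Several genes outside the fixed lists rose as well. Thbs1, which encodes the matrix protein thrombospondin-1, had a log2 fold change of 1.39 ± 0.29 (SE) at a mean level of 69093 normalized counts in the authors' deposited table. The matrix protease gene Adamts1 (1.24 ± 0.18) and Ltbp1, which encodes a binding protein of latent TGF-beta (1.13 ± 0.24), rose in the authors' deposited table too. So did the growth factor receptor genes Egfr (0.93 ± 0.21) and Igf1r (0.76 ± 0.16), and the kallikrein protease genes Klk11 (2.18 ± 0.24) and Klk10 (1.32 ± 0.32), which lie side by side on chromosome 7, in the authors' deposited table. Falls included the prostaglandin receptor gene Ptger3 (-1.94 ± 0.40) and Cck, which encodes the peptide cholecystokinin (-1.45 ± 0.29), in the authors' deposited table. The respiratory chain genes Cox7c (-1.15 ± 0.25) and Ndufs5 (-2.84 ± 0.76), neither in the fixed list, fell in the authors' deposited table, and Ndufs5 lost its call after the division by inflation (adjusted p = 0.0713) and with the length trend taken out (adjusted p = 0.0589). Cox7c and Ndufs5 had mean levels of only 170 and 45.9, against a median of 1690 in the nuclear oxidative phosphorylation list.

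Naip genes beside Ocln stood out, since all 6 listed, lying 43.6 to 294.4 kb from Ocln, had positive values. Of these, 3 were called, Naip5, Naip6 and the pseudogene Naip3. A candidate explanation is flanking DNA of another mouse strain carried with the targeted allele, and with Ocln and the Naip genes left out 1 of 70 genes within 5 Mb of Ocln was called (Mast4, lost with the length trend taken out at adjusted p = 0.0524), against 171 of 16148 elsewhere (odds ratio 1.35, 95 percent interval 0.03 to 7.9, Fisher exact two-sided p = 0.527), too few to decide. Strain differences elsewhere could leave blocks of called genes. Pairs of called genes within 500 kb that do not share a symbol stem numbered 13, against a median of 14 in 10000 reassignments of the calls. Of these 13, 3 paired Ocln with a Naip gene and 1 paired the related p200 genes Aim2 and Ifi204. The count lay in the middle 95 percent of the reassignments, 7 to 23, and leaves out blocks of genes that share a stem, so it cannot decide. Reads of 1 changed Naip gene assigned to its copies would give equal fold changes where the copies have few reads of their own, and among the 2 Naip genes with a mean level of at least 50 the log2 fold changes differed by -0.01 ± 0.50 (SE, taking them as independent), with a 95 percent interval of -0.99 to 0.97. Over all 6 Naip genes the fold changes were not equal (heterogeneity Q of 17.7 on 5 degrees of freedom), which speaks against read sharing alone, but the other 4 have mean levels under 50 and reads of their own could make them differ. Flanking DNA, strain background, read sharing and an effect of the knockout on these genes cannot be told apart, because the strains are not given in the sources used here and the tests rest on few genes.

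Luminal progenitor genes were listed higher. Transcript length as the whole cause is argued against by the list's median of 0.59, at percentile 100 of lists matched on level and length, whose middle 95 percent ran from -0.10 to 0.09. Neutrophil RNA as the source of Ltf, a gene of neutrophils too, is argued against by a rise of 103091 normalized counts for Ltf against 116 for S100a8 and S100a9 together, 891 times as much. A shift in the balance of luminal cell types toward progenitor cells may account for part of the pattern, since the hormone-sensing list was lower (cameraPR adjusted p = 0.0227), a call lost at a preset correlation of 0.05 (adjusted p = 0.103). Luminal cell types that differ between libraries of 1 genotype could also leave such lists shifted, since the median SE was 0.26 against 0.18 in lists matched on mean level for the progenitor list and 0.31 against 0.18 for the hormone-sensing list, both at percentile 100. The members did not move alike (heterogeneity Q of 132.2 on 19 degrees of freedom, and 74.6 on 18 without Ltf), so such a shift stays open beside changes of single genes within cells.

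G2/M genes were listed lower, with a median of -0.93 over 33 genes that all had negative values. Transcript length as the whole cause is argued against by percentile 0.0 among lists matched on level and length, whose middle 95 percent ran from -0.16 to 0.09. Fewer cycling cells in the knockout libraries may be a source, since the G1/S list was lower too (cameraPR adjusted p = 0.00714, and 0.103 at a preset correlation of 0.05). The G2/M median lay below that of G1/S by 0.68 (difference -0.68, permutation of members over genes, two-sided p = 1e-05, the smallest that 100000 permutations can give). That permutation treats members as independent and does not measure the spread between libraries. The difference does not decide for or against fewer cycling cells. Cycling that differs between libraries of 1 genotype could also leave such a list lower, since the median SE of its members was 0.45 against 0.26 in matched lists, at percentile 100. Which libraries drive it, and any direct effect of occludin on division, stay open, as no values per library were used here.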
